A study of Homo sapiens with 8 samples.

How the data were processed

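Total RNA, extracted with Trizol, was measured in Raji cells on 8 one-colour (Cy3) whole genome arrays of 44K format, with 4 groups (untreated, VP-16, NaB, NaB plus VP-16) of 2 biological replicates per the labels and 24 h of treatment. Each array held 43376 spots that were not controls, for 41000 probes. The values are fluorescence intensity per spot, deposited by the authors as files of Agilent Feature Extraction 9.5.1. Per the file headers, the processed intensity is corrected for background and for spatial trend within each array and is not scaled between arrays. The deposited series table holds the same intensity, and 360120 of its 360120 values were equal to those of the array files, so using it changes no result. All per-sample columns were matched to a sample, with 0 left over. No doses beyond the labels were used, and the microRNAs named in the study's title were not analysed here.

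The processed intensity was put on the log2 scale and the 75th percentile of each array was subtracted. Control spots and spots with an outlier flag were left out, spots of a probe were averaged, and probes well above background on at least 2 of the 8 arrays were kept, which left 27150 probes. Probes were named with the table of the GRCh38.p14 annotation, used for gene names alone: 23434 by accession, 2317 by symbol, 1043 by synonym, and 14206 kept the name in the array file. The probe with the highest mean stood for a gene, which gave 20424 genes, of which 12655 had a symbol in the table and 876 lacked a value on some array. Probe positions are those of the array annotation on hg17.

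Genes were compared with limma 3.58.1 (linear model, contrasts, moderated t) in R 4.3.3, with data.table (version 1.17.8) and statmod 1.5.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The model held the 4 groups and had 4 residual degrees of freedom, and its prior added 1.72. Of 7 comparisons, 3 set a treatment against untreated cells, 3 set treatments against each other and 1 tested the interaction of the drugs. P-values were adjusted over all genes of a comparison by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. The number of arrays limits the precision: with 2 per group, splitting the samples otherwise (which needs at least 3 per group) and testing for outlying samples were not possible.

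26 gene lists were written down before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. They held 563 genes, of which 496 were measured and 35 stood in 2 or more lists. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists of a comparison. Genes are named by a fixed rule: among called genes with one sign on both slides, the largest rises and falls well above background in both groups, those with the largest bounded folds, called members of each list with the smallest p, and a set of genes chosen in advance whatever their result. Results of some of these genes are withheld and left out of the text and figures. Families in the closing observations were chosen after the data were seen.

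The arrays of each replicate number were scanned together as 1 slide. Deviations from the group means correlated between groups at -0.07 to 0.28, so the numbers do not clearly pair the samples. The slide was therefore left out of the model and added as a block in an alternative whose values stand beside the results. The first 4 principal components held 28.5%, 19.1%, 16.3% and 12.5% of the variance. Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, no filter or a stricter filter on dim probes, the slide as a block, an intensity trend with robust fitting, a fit of only the groups compared, every probe on its own, the mean of a gene's probes, the series table, a 2-fold threshold, and leaving out each array. Changes that share the untreated arrays were compared with 20 simulated sets of unchanged groups, in which all groups had the same spread for a gene. The calculation was tested on simulated data of 19765 genes with the VP-16 design: 21 of 100 genes changed by 2-fold and 53 of 100 changed by 4-fold were recovered, with 4 unchanged genes called, and a list of 20 genes shifted by 0.5 log2 had a camera p of 1.45e-12 beside 0.518 for an unshifted list. Genes were drawn independently there, so the list values hold only for lists without correlation between genes.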

Results

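Gene expression was measured in Raji cells, a human B cell line from a Burkitt's lymphoma, on 8 one-colour arrays that hold 41000 probes each. The cells were untreated, or treated for 24 h with VP-16, with NaB, or with NaB plus VP-16, and each of the 4 groups had 2 biological replicates. VP-16 (etoposide) is a poison of topoisomerase II that leaves DNA double strand breaks. NaB (sodium butyrate) inhibits histone deacetylases. Each slide carried 1 array of every group, so the 2 replicates of a group lay on 2 slides. Between 63.1% and 64.5% of the spots were well above background on the first slide and between 57.1% and 60.6% on the second. The 75th percentile of the signal ran from 260 to 554 over the 8 arrays, and their number limits the precision of every value given here. Replicates correlated at 0.969 to 0.984 across genes. The median standard deviation between replicates was 0.11 log2 in untreated cells, 0.22 with VP-16, 0.14 with NaB and 0.16 with the combination. Unless stated otherwise, changes are log2 differences between group means with the standard error (SE), n = 2 per group, and p is adjusted over the 20424 genes tested. The SE comes from the model's 1 spread per gene, pooled over the 4 groups, so it does not measure the spread of only the groups compared.

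VP-16 against untreated cells asks which transcripts respond to the topoisomerase II poison alone. Some immediate early transcription factors were among the strongest falls. FOS fell by 5.27 (SE 0.22, adjusted p = 0.00210), EGR1 by 4.51 (SE 0.18, adjusted p = 0.00210), EGR2 by 4.26 (SE 0.15, adjusted p = 0.00210) and JUN by 3.43 (SE 0.21, adjusted p = 0.00623). CD69, an early activation marker of lymphocytes, fell by 4.31 (SE 0.16), and DHRS2, a reductase gene often raised by histone deacetylase inhibitors, fell by 4.28 (SE 0.17). On the 2 slides FOS changed by -5.22 and -5.32, EGR1 by -4.62 and -4.41, and DHRS2 by -4.41 and -4.15. With the slide as a block the adjusted p of FOS, EGR1, EGR2, CD69, DHRS2 and JUN was 0.0131. The size of a fall that ends near background depends on the background correction: with normexp FOS changed by -3.05, DHRS2 by -2.15 and SMAD1 by 1.37, all still called.

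Among the rises with VP-16, SMAD1, a signal transducer of bone morphogenetic proteins, gained 3.02 (SE 0.25, adjusted p = 0.0151). FHOD3, a formin that organises actin, gained 3.01 (SE 0.14, adjusted p = 0.00854), and IL7R, the interleukin 7 receptor, gained 2.52 (SE 0.38, adjusted p = 0.0329). The other large rises were LRRC2 at 2.30, GPD2 at 2.14 and CD24, a surface protein of developing B cells, at 1.76. SMAD1 gained 2.86 on the first slide and 3.17 on the second, with an adjusted p of 0.0253 in the blocked fit. The array annotation, on the hg17 genome build, places the SMAD1 probe on chromosome 4 from 146837824 to 146837883, the FOS probe on chromosome 14 from 74817967 to 74818026 and the EGR1 probe on chromosome 5 from 137832790 to 137832849. Exon and UTR annotation was not used.

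Some genes were not well above background on either array of the dimmer group. For these, a fold is given as a lower bound, taken against the lowest signal called well above background on those arrays, or the gene's own signal there where that was higher. With VP-16, CFI, the complement inhibitor factor I, was at least 11.5-fold higher (adjusted p = 0.0324) and LGALS2, a galectin, at least 4.24-fold higher (adjusted p = 0.0122). IFITM4P was at least 3.70-fold higher. JAKMIP3 was at least 15.7-fold lower (adjusted p = 0.0288), CFAP74 at least 13.5-fold lower, INHBE at least 5.20-fold lower and PHLDA2 at least 3.97-fold lower. In the blocked fit CFI (adjusted p = 0.0555), IFITM4P (0.0730) and JAKMIP3 (0.0517) no longer passed.

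Genes of the integrated stress response fell after VP-16. Of 20 measured ATF4 and ER stress genes, 12 fell and none rose over all genes tested, and 17 fell adjusted over the list alone. ATF3 fell by 3.10, ATF5 by 2.45, PPP1R15A, a phosphatase subunit that restarts translation, by 2.19 and DDIT3 (CHOP) by 2.16. ATF3 had a value in both groups on the first slide only, at -3.15. The list's median was -1.09, with a camera adjusted p of 7.96e-10 and an adjusted p = 0.144 with an estimated correlation. Among 24 NF-kB target genes, 5 fell, and 9 fell adjusted over the list alone. These included the chemokine CCL3 at -2.20, the inhibitors TNFAIP3 at -1.71 and NFKBIA at -1.57, and the chemokine receptor CCR7 at -1.31, which had a value in both groups on the first slide only and did not pass in the blocked fit (0.0628). That list's camera adjusted p was 0.000110, and the adjusted p = 0.144 with an estimated correlation.

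Of 26 p53 target genes, 1 rose and 6 fell with VP-16, both over all genes tested and adjusted over the list alone. The death receptors TNFRSF10B and FAS fell by 1.36 and 1.09, the kinase PLK3 by 1.02 and SESN2 by 1.02. CDKN1A, the cyclin dependent kinase inhibitor p21, fell by 0.89 (adjusted p = 0.0395, and 0.0615 in the blocked fit). TP53INP1 was the member that rose, by 0.92 (adjusted p = 0.0380). The camera adjusted p of the list was 0.00689 in the downward direction, and the adjusted p = 0.608 with an estimated correlation. Of 31 apoptosis regulators, 1 rose and 4 fell (4 and 10 adjusted over the list alone), with PMAIP1 (NOXA) at -1.11 and BIK at 0.76 (blocked 0.0712), and the camera adjusted p was 0.351.

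Mitosis genes lay higher with VP-16. Of 26 measured, 2 rose and none fell, and 5 rose adjusted over the list alone. The kinase AURKA gained 0.93 (SE 0.16, adjusted p = 0.0388) and the ubiquitin ligase subunit UBE2C gained 0.71 (SE 0.12, adjusted p = 0.0382), and neither passed in the blocked fit (0.0543 and 0.0696). The list's median was 0.41, the camera adjusted p was 1.3e-05 and the adjusted p = 0.144 with an estimated correlation. None of 26 DNA replication genes passed alone or over all genes by limma, where 4411 of all genes had an unadjusted p under 0.05. Their median was 0.20, with MCM2 at 0.63 and POLE2 at 0.72. The camera adjusted p of that list was 0.00433, and the adjusted p = 0.608 with an estimated correlation. Of 14 heat shock genes, HSPA1A, an inducible HSP70, rose by 1.44 (adjusted p = 0.0298, blocked 0.0570), and 2 rose adjusted over the list alone. The heat shock list had a camera adjusted p of 0.00397, and an adjusted p = 0.144 with an estimated correlation.

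The remaining lists did not pass camera with VP-16. Of 24 genes reported to respond to histone deacetylase inhibitors, none rose and 5 fell (3 and 6 adjusted over the list alone), among them DHRS2, the transcription factor KLF6 at -2.46, the histone gene H2BC5 at -1.70, with 1 of its 2 probes of opposite sign, and CDKN1A. The median of that list was 0.31 while its mean was -0.18 and its camera direction was down (adjusted p = 0.801). Of 17 histone genes 4 fell (6 adjusted over the list alone), with H4C3 at -1.0, H2AC6 at -0.87 and H1-2 at -0.79 (camera adjusted p = 0.111). SGK1 and DDIT4 were the members of the PI3K/Akt/mTOR pathway that fell, by 2.07 and 1.03, of 31 measured (2 adjusted over the list alone, camera adjusted p = 0.903). Among 27 B cell genes, MME, CD24 and TCL1A rose by 0.88, 1.76 and 0.96 and the phosphatase PTPN6 fell by 1.97 (the same number adjusted over the list alone, camera adjusted p = 0.760). CHEK2, a checkpoint kinase, rose by 0.76 and was the member called of 26 double strand break response genes (camera adjusted p = 0.210). OAS1 rose by 1.11 among 18 interferon stimulated genes (camera adjusted p = 0.157). The sterol enzymes CYP51A1 and MSMO1 fell by 1.18 and 0.80 among 19 cholesterol synthesis genes (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.125). CD86 rose by 1.73, with 1 of its 2 probes of opposite sign, and HLA-DQA1 fell by 0.82 among antigen presentation genes (camera adjusted p = 0.188). In the blocked fit H4C3 (0.0543), H2AC6 (0.0668), H1-2 (0.0737), DDIT4 (0.0566), MME (0.0593), TCL1A (0.0696), CHEK2 (0.0586), MSMO1 (0.0555) and HLA-DQA1 (0.0614) did not pass.

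Over the whole array, limma called 804 genes with VP-16, 227 higher and 577 lower, of which 535 also changed by at least 2-fold. With the slide as a block it called 356, 87 higher and 269 lower, of which 333 were among the 804. Leaving out the first or second untreated array left 7 or 2 calls, the first or second VP-16 array 353 or 80, and either NaB array 45.

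**Figure D1:**
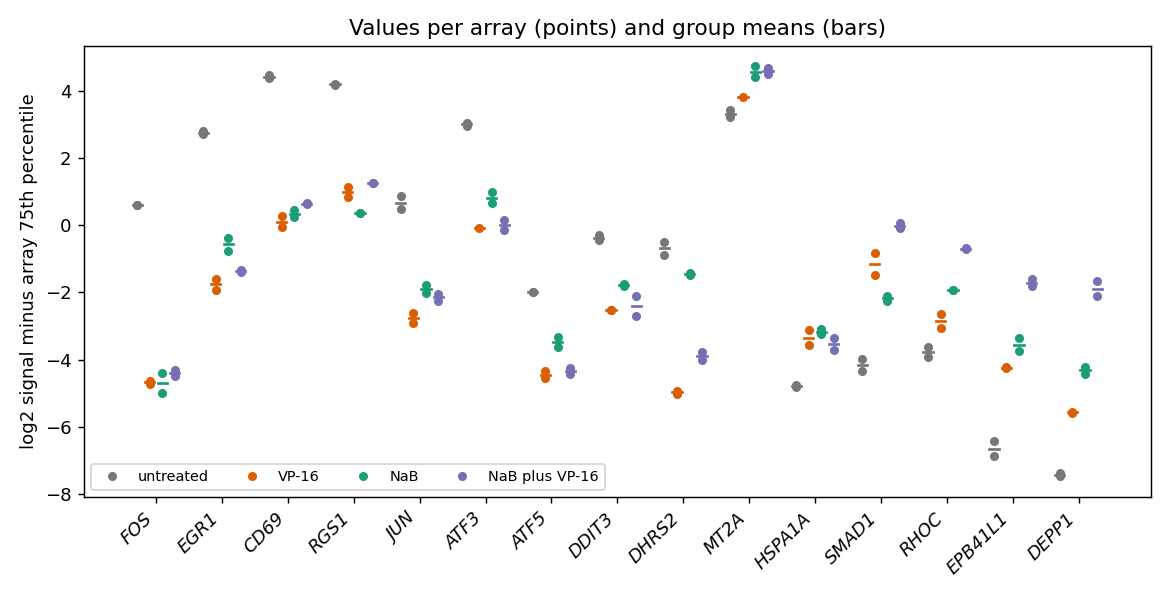
Signal of selected genes on each array (points) and the mean of each group (bars), as log2 signal minus the array's 75th percentile, for the 4 groups of 2 arrays. FOS lies at 0.60 in untreated cells and near -4.7 with either drug, while SMAD1 rises from -4.17 in untreated cells to -0.01 with the combination.

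NaB against untreated cells asks the same of the histone deacetylase inhibitor alone. CD69 fell by 4.08 (SE 0.16, adjusted p = 0.00273), RGS1, a regulator of G protein signalling in B cells, by 3.85 (SE 0.14, adjusted p = 0.00226) and EGR1 by 3.32 (SE 0.18, adjusted p = 0.00748). FOS fell by 5.31 (SE 0.22, adjusted p = 0.00273), although its second NaB array, at -5.01, lay below the lowest signal called well above background there (-4.64), so the size is not exact. JUN fell by 2.56 (SE 0.21, adjusted p = 0.0152). The phosphatase DUSP10 fell by 2.25 and ATF3 by 2.19. On the 2 slides CD69 changed by -4.02 and -4.13 and RGS1 by -3.87 and -3.83. In the blocked fit their adjusted p was 0.0218 and 0.0130.

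Among called genes with a symbol that were well above background in both groups, the largest rises with NaB were those of IBA57 and SMAD1. IBA57, a factor of iron-sulphur cluster assembly, rose by 2.15 (SE 0.40, adjusted p = 0.0478) and SMAD1 by 2.00 (SE 0.25, adjusted p = 0.0274). AIF1, a calcium binding protein of immune cells, rose by 1.88 (SE 0.13, adjusted p = 0.0128), the small GTPase RHOC by 1.83 (SE 0.19, adjusted p = 0.0211), the heat shock protein HSPA2 by 1.78 and S100A10 by 1.62. The IBA57 rise was 1.74 on the first slide and 2.55 on the second, and its blocked adjusted p was 0.0805. ANXA2, the membrane partner of S100A10, was at least 4.83-fold higher (adjusted p = 0.0152). IL3RA, a subunit of the interleukin 3 receptor, was at least 3.76-fold higher, EPB41L1 at least 3.17-fold higher and MALL at least 2.74-fold higher. JAKMIP3 was at least 10.4-fold lower (adjusted p = 0.0316, blocked 0.0576), RGMA at least 2.60-fold lower, GBP3 at least 2.18-fold lower and DOP1A at least 2.16-fold lower. RGMA (0.0624) and GBP3 (0.0538) did not pass in the blocked fit either.

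Genes reported to respond to histone deacetylase inhibitors moved both ways with NaB. Of 24 measured, 5 rose and 1 fell, and 9 rose and 4 fell adjusted over the list alone. The rises included the metallothioneins MT2A at 1.26, MT1G at 1.24 and MT1E at 1.15, which bind metals, and KLF6 fell by 1.82. The 3 metallothioneins did not pass in the blocked fit (0.0549, 0.0516 and 0.0573). CDKN1A stood at -0.50 (adjusted p = 0.110) and DHRS2 at -0.77 (adjusted p = 0.0646). The list's median was 0.35 beside 0.12 for all genes, and the camera adjusted p was 0.400. Among 29 chromatin enzymes, DNMT1, the maintenance DNA methyltransferase, rose by 0.78 and HDAC1 by 0.66 (2 adjusted over the list alone, camera adjusted p = 0.423, blocked adjusted p = 0.0690 and 0.0773). None of 17 histone genes passed over all genes or adjusted over the list alone in limma, which had 5287 of all genes at an unadjusted p under 0.05. H2BC4 stood at 0.67 and H1-10 at 0.90, and the list's camera adjusted p was 0.0978.

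Of the 20 ATF4 and ER stress genes, 2 rose and 7 fell with NaB (3 and 9 adjusted over the list alone). PPP1R15A fell by 1.93, ATF5 by 1.48 and DDIT3 by 1.42 (blocked 0.0606). Of the 26 p53 target genes, 4 fell (2 higher and 8 lower adjusted over the list alone). These 4 were PMAIP1 at -1.18, FAS at -1.12, MDM2, the ubiquitin ligase of p53, at -1.03 and PLK3 at -0.92, and in the blocked fit none of them passed (0.0516, 0.0503, 0.0534 and 0.0583). The camera adjusted p was 0.0218 for the stress list and 0.0113 for the p53 list, and both had an adjusted p = 0.521 with an estimated correlation. BMF, a proapoptotic member of the BCL2 family, rose by 0.96 (blocked 0.0654) among 31 apoptosis regulators, of which 1 rose and 2 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.400).

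4 lists lay higher with NaB by camera. MYC target genes had a median of 0.26 and a camera adjusted p of 0.0133 (adjusted p = 0.521 with an estimated correlation, as for the other 3), with PPAN, a ribosome assembly factor, rising by 0.74 as the member called of 30 (4 adjusted over the list alone). Heat shock genes had a camera adjusted p of 0.0365, with HSPA1A at 1.61 and the cochaperone DNAJB1 at 0.80 as the 2 called (3 adjusted over the list alone). The 23 ribosomal protein genes (median 0.26, adjusted p = 0.0365) and the 24 antigen presentation genes (median 0.23, adjusted p = 0.0438) held no called member, either way of adjusting. PPAN (0.0758), HSPA1A (0.0557) and DNAJB1 (0.0683) did not pass in the blocked fit. With quantile scaling the adjusted p was 0.229 for the MYC and heat shock lists, 0.673 for the ribosomal list and 0.312 for antigen presentation, and with the block it was 0.0520 for heat shock and 0.0619 for antigen presentation.

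Mitosis genes included 4 rises with NaB of 26 measured (8 higher and 1 lower adjusted over the list alone). AURKA rose by 1.02, KIF20A by 0.94, PLK1 by 0.81 and AURKB by 0.68, and the camera adjusted p was 0.164. None of these passed in the blocked fit (0.0534, 0.0661, 0.0745 and 0.0707). In the PI3K/Akt/mTOR pathway 2 rose and 2 fell of 31 (3 and 4 adjusted over the list alone, camera adjusted p = 0.742). SGK1 fell by 1.74 and RICTOR, the defining subunit of mTOR complex 2, by 1.25. DDIT4, an inhibitor of mTOR complex 1, rose by 0.93 and PIK3CD, the catalytic subunit of PI3K found in lymphocytes, by 0.65. Of 26 double strand break response genes, BRCA2 fell by 1.46 (SE 0.15, adjusted p = 0.0226, blocked 0.0474) and XRCC6 (Ku70) rose by 0.61 (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.713). Plasma cell genes included DERL3 at 1.03 (camera adjusted p = 0.510), and OAS1 and BST2 rose by 0.81 and 0.66 among interferon stimulated genes (camera adjusted p = 0.594). RICTOR (0.0617), DDIT4 (0.0677), XRCC6 (0.072), DERL3 (0.0566), OAS1 (0.0667) and BST2 (0.0762) did not pass in the blocked fit.

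Over all genes limma called 976 with NaB, 358 higher and 618 lower, and 538 of them changed by at least 2-fold. The lean towards falls was smaller with the strict filter (941 higher, 1046 lower) and with an intensity trend (1101 higher, 1106 lower). The blocked fit called 210, 36 higher and 174 lower, of which 206 were among the 976. The count was 0 without either untreated array, where 3261 and 2826 genes had an unadjusted p under 0.05. It was 15 or 25 without either NaB array, and 136 or 137 without either combination array.

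NaB plus VP-16 against untreated cells asks what the drugs do together. SMAD1 rose by 4.16 (SE 0.25, adjusted p = 0.00231), CTSZ, a lysosomal protease, by 3.18 (SE 0.43, adjusted p = 0.00940) and RHOC by 3.08 (SE 0.19, adjusted p = 0.00231). APOBR, a lipoprotein receptor, rose by 2.82 and PLPPR2 by 3.08. PPP3R1, the regulatory subunit of calcineurin, rose by 2.79 on the probe used, and its other probe changed in the opposite direction. EGR1 fell by 4.11 (SE 0.18, adjusted p = 0.00137), CD69 by 3.78 (SE 0.16, adjusted p = 0.00137) and EGR2 by 3.22. PHACTR1 fell by 3.47 and NDRG3 by 3.21. SMAD1 changed by 4.26 and 4.06 on the 2 slides and EGR1 by -4.09 and -4.12, while PLPPR2 changed by 1.75 and 4.42. The blocked adjusted p was 0.00847 for SMAD1 and RHOC and 0.00813 for EGR1 and CD69.

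Of genes dim in untreated cells, EPB41L1, a protein of the membrane skeleton, was at least 11.4-fold higher with the combination (adjusted p = 0.00137) and DEPP1, an autophagy regulator induced by FOXO factors, at least 10-fold higher (adjusted p = 0.00137). CCL23, a chemokine, was at least 8.73-fold higher and LGALS2 at least 7.77-fold higher. JAKMIP3 was at least 12.3-fold lower (adjusted p = 0.00621), RBM48 at least 4.62-fold lower, SLC23A1 at least 3.99-fold lower and KLK13 at least 3.13-fold lower. The KLK13 call was lost in the blocked fit (adjusted p = 0.0582).

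With the combination, 14 of 20 ATF4 and ER stress genes fell and none rose, which was also the count adjusted over the list alone. ATF3 fell by 3.0, ATF5 by 2.35, PPP1R15A by 2.20 and DDIT3 by 2.04. The list's median was -0.93, the camera adjusted p was 1.07e-06 and the adjusted p = 0.357 with an estimated correlation. Of 26 p53 target genes 4 rose and 9 fell (7 and 9 adjusted over the list alone, camera adjusted p = 0.132). TP53INP1 rose by 1.59, while TNFRSF10B fell by 1.42, FAS by 1.40 and PMAIP1 by 1.15. Of 31 apoptosis regulators 8 rose and 6 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.991), with BMF at 1.48 and BCL2L11 (BIM) at -1.18, where 1 of 4 BCL2L11 probes had the opposite sign. The apoptosis list had a median of 0.12 and a mean of 0.03 but a camera direction of down.

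Cell cycle genes lay higher with the combination. Of 26 mitosis genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with AURKA at 1.5, UBE2C at 1.13, BIRC5 (survivin) at 1.05 and PLK1 at 0.87. Of 26 DNA replication genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), with MCM2 at 1.04, CDT1 at 0.96, CDC25A at 0.79 and CCNE2 at -1.35. The camera adjusted p was 0.0211 for mitosis and 0.0159 for replication, and the adjusted p = 0.548 and 0.714 with an estimated correlation. Of 11 CDK inhibitors and cyclins, CCND3 rose by 1.33, CDKN2C by 1.0 and CDKN2B by 1.80 (the last dim in untreated cells, at least 1.1-fold) and CDKN1A fell by 0.62 (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.752). Ribosomal protein genes had a median of 0.32 (camera adjusted p = 0.0211), with RPS9 at 0.66 and RPS3 at 0.52 as the 2 called of 23 (1 adjusted over the list alone). Heat shock genes had HSPA6 at 1.61, HSPA1A at 1.26 and DNAJB1 at 0.92 as the 3 called of 14, both ways of adjusting (camera adjusted p = 0.0385). The ribosomal and heat shock lists had an adjusted p = 0.714 and 0.548 with an estimated correlation. With quantile scaling it was 0.442 for the ribosomal list, 0.171 for heat shock and 0.122 for mitosis and replication.

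Genes of DNA repair and chromatin also changed with the combination, though their lists did not pass camera. CHEK2 rose by 1.51 (SE 0.12, adjusted p = 0.00357) and XRCC5 (Ku80), which binds broken DNA ends, by 0.71, while NBN fell by 1.04. That made 6 rises and 2 falls of 26 double strand break response genes, the same counts adjusted over the list alone (camera adjusted p = 0.438). Of 29 chromatin enzymes 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.812). The de novo methyltransferase DNMT3B rose by 1.08, HDAC1 rose by 0.80, the acetyltransferase EP300 fell by 1.71 and HDAC10 fell by 1.51, where 1 of the 2 HDAC10 probes had the opposite sign. Of 24 genes responsive to deacetylase inhibitors 11 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.780). TUBB3, the neuronal tubulin, rose by 1.29 and MT1G by 1.42, and DHRS2 fell by 3.19 and KLF6 by 1.96. H2BC5 fell by 1.45 as the histone gene called of 17 (camera adjusted p = 0.812).

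B cell and immune genes with the combination included the costimulatory ligand CD86, which rose by 2.72 (SE 0.20, adjusted p = 0.00333). TCL1A rose by 1.64 and CD24 by 1.85, whereas PTPN6 fell by 1.40 and EBF1, a factor of B cell identity, by 1.05. Of 27 B cell genes 3 rose and 2 fell (camera adjusted p = 0.761), of 24 antigen presentation genes 5 rose and 1 fell (0.761), and of 15 plasma cell genes 1 rose (0.319), the same counts adjusted over each list alone. HLA-DOA rose by 0.89, but 2 of its 4 probes had the opposite sign. Of 24 NF-kB target genes 1 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.272), with TNFAIP3 at -1.41, NFKBIA at -1.22 and CCL3 at -1.1. OAS1 rose by 1.36, IFI35 by 1.06 and BST2 by 0.65 among 18 interferon stimulated genes with 4 rises and 2 falls (camera adjusted p = 0.752). MSMO1 fell by 2.09, with 1 of its 2 probes of opposite sign, and CYP51A1 by 0.89, while MVD rose by 0.80, of 19 cholesterol synthesis genes (3 higher and 4 lower, 5 and 5 adjusted over the list alone, camera adjusted p = 0.820). AHCY, BOP1, TERT and CAD were the 4 MYC target genes called of 30, with rises of 0.78, 0.91, 0.75 and 0.69 (4 adjusted over the list alone, camera adjusted p = 0.132).

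Markers of other cell types were measured beside these groups. With the combination NKG7, LCK and CD247 rose by 1.55, 1.31 and 0.48 among 9 T and NK cell markers (camera adjusted p = 0.132), and CD33 rose by 1.87 among 11 myeloid markers (0.780). PECAM1, at least 3.06-fold, and ACTA2, by 0.83, rose among 10 epithelial and stromal markers (0.135), and HBB, EPOR and HBA1 rose among 7 erythroid and megakaryocyte markers (0.209). HBB and HBA1 were dim in untreated cells, and rose at least 1.39-fold and at least 1.85-fold, HBA1 with a value on 1 combination array. CD247 did not pass in the blocked fit (0.0524). Adjusted over the list alone the counts were 3 for T and NK cell, 1 for myeloid, 3 for epithelial and stromal and 4 for erythroid markers. Of 13 neuronal genes TUBB3 rose by 1.29, STMN3 rose by 1.08, with 1 of its 2 probes of opposite sign, and NEFM fell by 1.08 (0.821). FOS, which fell by 5.0, was the gene called of 17 reported targets of miR-143, miR-145 and miR-101 (0.761). That list gave 0 rises and 1 fall with each drug alone as well, with camera adjusted p of 0.484 for VP-16 and 0.247 for NaB. Those microRNAs were not analysed here.

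Over all genes limma called 4299 with the combination, 2332 higher and 1967 lower, and of the 2026 that changed by at least 2-fold 819 were higher and 1207 lower. The blocked fit called 3939, 2075 higher and 1864 lower, of which 3603 were among the 4299. The count was 233 (82 higher, 151 lower) or 309 (95 higher, 214 lower) without the first or second untreated array, and 2710 or 1669 without either combination array.

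**Figure D2:**
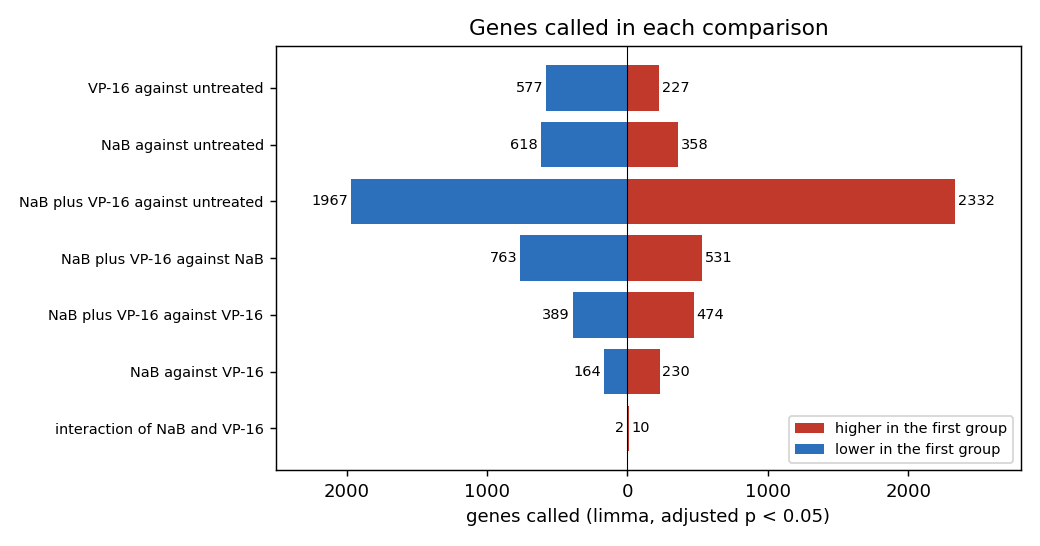
Number of genes called higher (right) or lower (left) by limma at an adjusted p under 0.05 in each of the 7 comparisons. The combination against untreated has 2332 higher and 1967 lower, and the interaction has 10 and 2.

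**Figure D3:**
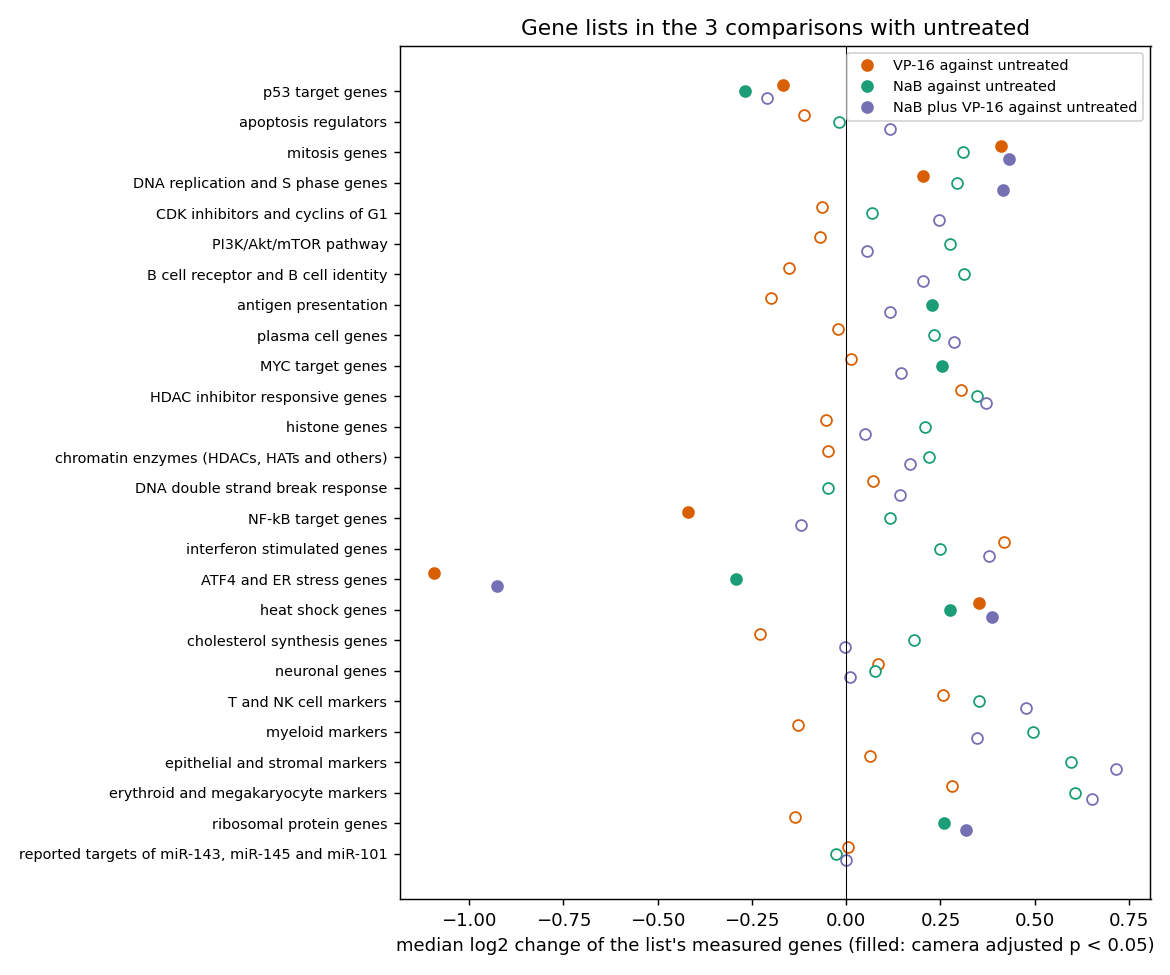
Median log2 change of the measured genes of each of the 26 lists in the 3 comparisons with untreated cells, filled where the camera adjusted p with a preset correlation is under 0.05. None of the filled points passes with an estimated correlation, and the ATF4 and ER stress list lies lowest, at -1.09 with VP-16 and -0.93 with the combination.

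Genes of the PI3K and Akt pathway and other genes chosen in advance were read whatever their result. HDAC1 rose with NaB by 0.66 (SE 0.12, adjusted p = 0.0462) and with the combination by 0.80 (SE 0.12, adjusted p = 0.0118). MYC stood at 0.20 with VP-16, 0.76 with NaB (adjusted p = 0.0599) and 0.01 with the combination. BCL2 stood at -0.86 with VP-16 (adjusted p = 0.0515), -0.66 with NaB and -0.23 with the combination, and MCL1 at -0.20, -0.03 and -0.00. 1 of the 2 BCL2 probes had the opposite sign in each of these comparisons. The targets of VP-16, TOP2A and TOP2B, stood at 0.51 and 0.03 with VP-16, 0.08 and -0.19 with NaB, and 0.15 and -0.07 with the combination. HDAC2 stood at -0.17, 0.22 and 0.15 in the same order, HDAC3 at -0.17, 0.46 and 0.32, and EZH2 at -0.49, -0.32 and -0.21.

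AKT1 stood at 0.74 with VP-16, 0.69 with NaB and 0.24 with the combination. AKT2 was dim in untreated cells, with lower bounds of 1.73-fold, 1.78-fold and 1.36-fold higher and no call. Among PI3K subunits PIK3CA stood at -0.37, -0.54 and -0.74 (adjusted p = 0.0560 with the combination, and 0.0227 in the blocked fit), PIK3CB at -0.06, 0.36 and -0.70, PIK3CG at 0.58, 0.28 and 0.38 and PIK3R1 at -0.07, -0.28 and -0.17. PIK3CD rose by 0.65 with NaB (adjusted p = 0.0482, blocked 0.0755) and stood at -0.14 with VP-16 and 0.15 with the combination, where 2 of its 3 probes had the opposite sign and the mean of its probes was a called fall (-0.87, adjusted p = 0.0172). None of AKT1, AKT2, PIK3CA, PIK3CB, PIK3CG and PIK3R1 passed in any of the 3 comparisons. With the combination 2 pathway members fell of 31, SGK1 by 1.46 and RPS6KB1 by 0.73 (1 of its 4 probes of opposite sign), also when adjusted over the list alone (camera adjusted p = 0.780).

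**Figure D4:**
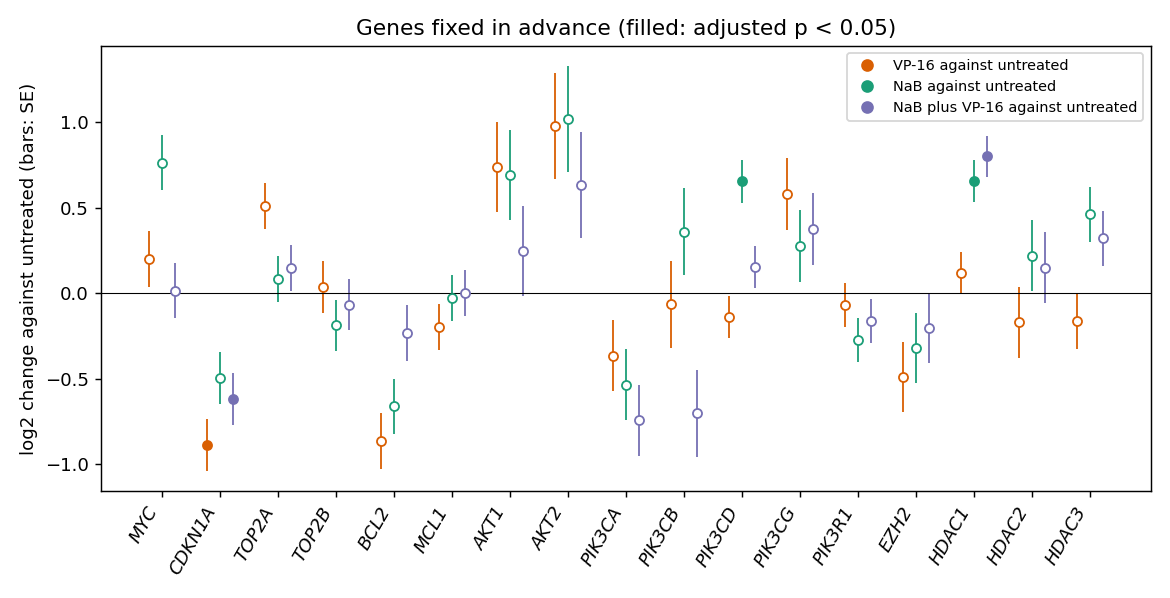
Log2 change against untreated cells of genes chosen in advance, with the SE as bars, for VP-16, NaB and the combination, filled where the adjusted p is under 0.05. HDAC1 is filled with NaB at 0.66 and with the combination at 0.80.

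The combination against NaB alone asks what VP-16 adds to NaB. CTSZ was higher by 3.32 (SE 0.43, adjusted p = 0.0220), PPP3R1 by 3.03 (1 of its 2 probes of opposite sign), RASGEF1A by 2.52 (blocked 0.0561) and DEPP1 by 2.43 (SE 0.18, adjusted p = 0.00853). NDRG3 was lower, at -3.60 (SE 0.18, adjusted p = 0.00617), as were the small GTPase RHOF at -3.40 (1 of its 4 probes of opposite sign) and TBCCD1 at -3.37. DHRS2 was lower at -2.42 (adjusted p = 0.00808). Of the repair genes, BRCA2, BRCA1 and CHEK2 were higher by 1.72, 1.12 and 1.03, and PRKDC was lower at -0.95 (adjusted p = 0.0423, blocked 0.0587). BRCA2 lay at -1.22 with the combination and -2.94 with NaB, beside -1.49 in untreated cells. Of 20 ATF4 and ER stress genes 5 were lower and none higher (10 lower adjusted over the list alone), among them the chaperone HSPA5 (BiP) at -1.44, CHAC1 at -1.40 and DDIT4 at -1.20. This list had a camera adjusted p of 5.46e-05, and an adjusted p = 0.577 with an estimated correlation, and the other 25 lists did not pass. In all, 1294 genes were called, 531 higher and 763 lower. The blocked fit called 765, of which 702 were shared, and leaving out the first NaB array left 0, with 3939 genes at an unadjusted p under 0.05.

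The combination against VP-16 alone asks what NaB adds to VP-16. L3MBTL3, a chromatin reader of methylated histones, was higher by 3.03 (SE 0.28, adjusted p = 0.0232), CTSZ by 2.93, KLHL14 by 2.76 and PPP3R1 by 2.54, again with 1 of its 2 probes of opposite sign. CAMK2N2, an inhibitor of calcium/calmodulin dependent kinase II, was lower at -2.69 (SE 0.33, adjusted p = 0.0302), LCE2D at -2.57, TOX2 at -2.47 and NDRG3 at -2.25. In the blocked fit CTSZ (0.0547), KLHL14 (0.0511), PPP3R1 (0.0565), CAMK2N2 (0.0515) and TOX2 (0.0565) did not pass. The 23 ribosomal protein genes had a median of 0.46 beside 0.14 for all genes, with RPS9 and RPL27 higher by 0.95 and 0.64 (14 adjusted over the list alone, camera adjusted p = 8.47e-05, and 0.348 with quantile scaling). Its adjusted p = 0.733 with an estimated correlation. NF-kB target genes (0.0437), antigen presentation (0.0461) and genes responsive to deacetylase inhibitors (0.0493) lay higher, and had an adjusted p = 0.733, 0.747 and 0.747 with an estimated correlation, 0.0860 each with the block, and 0.0927, 0.348 and 0.0927 with quantile scaling. They held CCL3 at 1.09, HLA-DMB at 0.75 and S100A4, dim with VP-16, at least 2.10-fold higher among their called members. HLA-DMB (0.0671), S100A4 (0.0602) and RPL27 (0.0664) did not pass in the blocked fit, and 1 of the 2 HLA-DMB probes had the opposite sign. In all, 863 genes were called, 474 higher and 389 lower. The blocked fit called 313, 150 higher and 163 lower, of which 271 were shared. Requiring 2-fold as well gave 239 higher and 300 lower, normexp 64 and 73, and the mean of probes 279 and 284. More were higher than lower with quantile normalization, median scaling, the strict filter and the intensity trend. Leaving out any array but the first combination array gave 0 calls, with 4204 to 5725 genes at an unadjusted p under 0.05, and leaving out that array gave 809, of which 286 were higher and 523 lower and 320 were shared.

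NaB against VP-16 sets the drugs side by side. DHRS2 was higher with NaB by 3.51 (SE 0.17, adjusted p = 0.0144), TEX19 by 3.10 (SE 0.14, adjusted p = 0.0144), the linker histone H1-10 by 2.15 and RHOF by 2.03. FHOD3 was lower at -2.19 (SE 0.14, adjusted p = 0.0324), LACC1 at -1.94, PCDH9 at -1.69 and BRCA2 at -1.62. Histone genes lay higher with NaB, with 5 called of 17 (7 adjusted over the list alone), including H2BC5 at 1.76, H1-5 at 1.27 and H1-2 at 1.12. 5 of 20 ATF4 and ER stress genes (14 higher and 2 lower adjusted over the list alone) and 5 of 24 NF-kB target genes (11 adjusted over the list alone) were higher too, with DDIT4 at 1.95, CHAC1 at 1.72, IL10 at 1.29 and CD83 at 1.02. The camera adjusted p was 0.000880 for histone genes and 0.000152 for the stress and NF-kB lists, and the adjusted p = 0.353 and 0.346 with an estimated correlation. Ribosomal protein genes (0.000152, and 0.444 with quantile scaling), antigen presentation (0.000678), genes responsive to deacetylase inhibitors (0.0297) and cholesterol synthesis (0.0297) lay higher and mitosis genes (0.0297) lower. With an estimated correlation their adjusted p was 0.346, 0.346, 0.353, 0.528 and 0.353, and the cholesterol list also failed with the block (0.0686) and with quantile scaling (0.0514). Limma called 394 genes, 230 higher and 164 lower. With the slide as a block it called 0, where 5259 genes had an unadjusted p under 0.05, and DHRS2 had a blocked adjusted p of 0.0649.

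Calls of the drugs overlapped. VP-16 and NaB shared 90 genes called higher and 216 called lower, where independent calls would share 3.98 and 17.5, which ignores the shared untreated arrays, and 3 genes went opposite ways. VP-16 shared 189 higher and 456 lower with the combination (25.9 and 55.6 if independent), and NaB shared 279 and 424 (40.9 and 59.5). In all 3 comparisons 85 genes were called higher and 205 lower, and 1946 higher and 1287 lower were called with the combination only, which is no test of a difference from the single drugs. All 3 comparisons share the untreated arrays, which alone makes their changes correlate. Across genes, which are not independent replicates, the VP-16 and NaB changes correlated at 0.478, beside 0.499 simulated for unchanged groups, and their covariance was 0.183 beside 0.0966. VP-16 and the combination correlated at 0.551 (simulated 0.503, covariance 0.278 beside 0.0974), and NaB and the combination at 0.561 (0.501, 0.277 beside 0.0968). The simulation gave all groups the same spread for a gene, which by itself sets its correlations near 0.5. Whether the drugs agree beyond the shared arrays cannot be read from them. Untreated replicates varied least (median SD 0.11 log2, beside 0.22 with VP-16, 0.14 with NaB and 0.16 with the combination), so the simulated covariances may be too high. The covariance differences, 0.0869, 0.181 and 0.180, are rough estimates of the part not owed to replicate noise of the shared untreated arrays. A state common to both untreated cultures would stay in them. With the untreated arrays taken from different slides the correlations were 0.264, 0.311 and 0.346. These are changes of 1 treated array less 1 untreated array, so noise of single arrays also lowers them. Between the slides, the change of a treatment correlated with itself at 0.375 (VP-16), 0.454 (NaB) and 0.461 (combination).

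The interaction asks whether the drugs together differ from the sum of their separate log2 changes. By limma 12 genes were called, 10 with a positive value and 2 with a negative one, and 6 in the blocked fit, 5 of them shared. CD69 had an interaction of 4.61 (SE 0.23, adjusted p = 0.0111), RGS1 of 4.11 (SE 0.19, adjusted p = 0.0111), EGR1 of 3.73 (SE 0.25, adjusted p = 0.0318) and SGK1 of 2.35 (SE 0.17, adjusted p = 0.0332). FOS had 5.58, which rests on its inexact level with NaB, KLF6 2.32 and CCL3 2.25. The sum of both FOS falls would end below the lowest signals called well above background on the combination arrays (-5.32 and -5.18). A positive value of FOS was therefore bound to follow. On the 2 slides CD69 gave 4.75 and 4.47, and the blocked adjusted p was 0.0456 for CD69, RGS1 and FOS and 0.103 for EGR1, SGK1, KLF6 and CCL3. Each of these 7 genes fell with either drug and fell less with the combination than the sum of both falls. FOS lay at -4.40 with the combination, beside -4.67 with VP-16 and -4.71 with NaB. In the same order RGS1 lay at 1.26, 0.99 and 0.36 and CCL3 at 2.78, 1.69 and 2.73, each near its level with the drug that lowered it less. EGR1 lay at -1.35, -1.76 and -0.57, between its levels with the single drugs. The call count was 0 without either untreated array or the first NaB array, where 2244, 2276 and 2995 genes had an unadjusted p under 0.05, and 148 without the first combination array, where the signs turned to 37 positive and 111 negative. The p53 target list had a median interaction of 0.38 (camera adjusted p = 0.00660) and the ATF4 and ER stress list 0.46 (0.0477, blocked 0.10), with none of their genes called over all genes and 8, and 7 with 1 negative, adjusted over the list alone. Both had an adjusted p = 0.659 with an estimated correlation, and the other 24 lists did not pass.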

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

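All tests of explanations in this part were chosen after the results were seen.

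The interaction tests whether one drug's effect differs with the other drug present. It picked out EGR2 at 5.70, FOS at 5.58, CD69 at 4.61, RGS1 at 4.11, EGR1 at 3.73, NR4A3 at 3.66, SGK1 at 2.35, KLF6 at 2.32, CCL3 at 2.25 and CCL3L3 at 2.17, as well as ENST00000373014 at -2.70 and the unnamed probe A_32_P73707 at -2.85. With NaB, EGR2 averaged -5.11, NR4A3 -5.05 and FOS -4.71, near the lowest signals called well above background on those arrays (-5.73 and -4.64), so the sizes of these 3 are not exact. For each of the 3, the sum of both falls would end below the lowest signals called well above background on the combination arrays (-5.32 and -5.18). A positive value was therefore bound to follow, and its sign alone is no evidence against additive falls. With the combination EGR2, NR4A3 and FOS lay 1.44, 1.25 and 0.31 above their levels with NaB. The interaction also picked out the p53 target list at a median of 0.38 and the ATF4 and ER stress list at 0.46, neither of which passed with an estimated correlation (adjusted p = 0.659). In the blocked fit EGR2, FOS, CD69, RGS1 and NR4A3 passed (adjusted p = 0.0456) and the other 7 did not (0.103). No gene was called by limma without either untreated array or the first NaB array (2244, 2276 and 2995 at an unadjusted p under 0.05).

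Of genes called lower with VP-16 and with NaB, the combination's change was a median of 1.11 times the mean single change (quartiles 0.853 and 1.35, 216 genes), not the sum. The tables argue against the floor of the signal, since 179 of 216 (82.9%) were well above background on all 6 treated arrays. For the combination's change they also argue against a single slide, since the median ratio was 1.1 on one slide (quartiles 0.865 and 1.36) and 1.06 on the other. For the single drugs the slides were not tested, because picking called genes favours falls shared by both slides. 2 explanations stay open, and both need this ratio: the untreated cultures may have stood in an induced state, or either drug may lower the same program, for which the median interaction over these genes was 1.17. The design has no second set of untreated cells that would separate them. The genes were picked for being lower in both single comparisons, which share the untreated arrays, so part of the interaction can come from the picking.

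More genes were called with the combination than with either drug. The lowest ratio of its calls to the larger single count was 3.29 over quantile normalization, median scaling and normexp, which argues against the choice of scaling. Normexp keeps the scaling by the array's percentile and changes the background correction. All 3 set the arrays to a common level, so a shift of all genes together was not tested. At one unadjusted p, 0.0105, the ratio was 1.77 (1998 genes with VP-16 and 2430 with NaB), so how much of the larger count comes from the adjusted threshold cannot be told apart from larger changes. Larger changes with both drugs may contribute: the combination's variance across genes beyond simulated noise was 0.460, beside 0.209 for VP-16 and 0.190 for NaB, a ratio of 2.20 to the larger. The same noise was taken off each, though replicates of the groups varied unequally. An additive sum of the drugs would give 0.573.

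DHRS2, CDKN1A and KLF6, often raised by deacetylase inhibitors, were not higher with NaB, and their highest value under 3 other scalings was -0.48, which argues against scaling. An exchange of NaB and VP-16 labels would not account for the missing rise. The same genes were lower with VP-16 too, where the highest of the 3, CDKN1A, was -0.89 against untreated cells (SE 0.15). Since the 3 genes were lower than untreated under either labelling, they cannot tell which labelling is right. For an exchange of NaB and untreated labels, the list's median less that of all genes was 0.23 and camera gave an adjusted p = 0.400, so it cannot be told apart from correct labels by this list. Metallothioneins, some of them in the list, run as the labels say, with 6 of 9 called higher with NaB, 7 with the combination and 0 with VP-16. The contrast is one of degree: with VP-16 their changes ran from 0.18 to 0.81 with a median of 0.50, beside a median of 1.04 with NaB. MT1G was 1.03 higher with the combination than with VP-16 (blocked adjusted p = 0.0547). This family was picked after the data were seen and was not tested as a set, so its rise with NaB is weak support for the labels. Under an exchange its response to NaB would have to change sign when VP-16 is present, which no table excludes. A different response of these genes in Raji cells also stays open, and no test here addressed it.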

How the results depend on the processing

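Counts of called genes moved with many settings and are given in the order VP-16, NaB, combination (each against untreated), combination against NaB, combination against VP-16, NaB against VP-16, interaction. With normexp the first 6 were 330, 180, 2080, 448, 137 and 136, and the share higher with NaB was 10.6% beside 36.7%. Quantile normalization gave 803 for NaB against VP-16 and 58 for the interaction (55.2% positive beside 83.3%). Median scaling gave 555 for NaB, 214 for NaB against VP-16, and 70.6% positive for the interaction. Without a filter the counts were 138, 57, 2206, 183, 0 (limma, 5646 at an unadjusted p under 0.05), 2 and 4. The strict filter gave 1297 (VP-16), 1987 (NaB, 941 higher and 1046 lower), 2015, 2108, 1648 and 234 for the last 4. An intensity trend with robust fitting gave 1325, 2207 (1101 higher and 1106 lower), 2153, 2269, 1644 and 187 for the same 6. With the slide as a block they were 356, 210, 765, 313, 0 (5259 at an unadjusted p under 0.05) and 6. Fitting only the groups compared gave 0 by limma for VP-16, NaB and the 3 comparisons between treatments (3805, 6476, 4818, 3368 and 3583 at an unadjusted p under 0.05). The mean of probes gave 563 for the combination against VP-16. Requiring 2-fold as well gave 535, 538, 2026, 814 and 539 for the first 5. With normexp the median change of all genes was 0.24 for NaB against VP-16, beside 0.13. The cause was not tested.

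Leaving out 1 array, whose partner is assumed to vary like the other groups, gave 2 to 353, 0 to 1117, 233 to 5034, 0 to 1599, 0 to 809, 0 to 6 and 0 to 148 calls in that order. Removing either untreated array moved every count (VP-16 7 and 2, NaB 0 and 0, combination 233 and 309). So did removing either NaB array for VP-16 (45 and 45) and NaB (15 and 25), either combination array for VP-16 (320 and 326), NaB (136 and 137) and, for the combination, the first (2710) and second (1669), and either VP-16 array for VP-16 (353 and 80). For the combination against NaB, 67 and 67 were left without an untreated, 0 and 35 without a NaB, and 785 and 157 without a combination array. For the interaction, 3 and 3 were left without a VP-16 array, 0 and 3 without a NaB array, and 148 (37 positive, 111 negative) and 2 without a combination array. Correlations of single-array changes with untreated arrays of different slides were 0.264, 0.311 and 0.346, and VP-16 with the combination gave 0.603 under the strict filter.

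3 gene values reversed: HBB with VP-16 (-0.080 with normexp), and HLA-DOA (-0.22, adjusted p = 0.843) and PIK3CD (-0.87, a called fall at 0.0172) with the combination by the mean of probes. Of the values of 266 named results, 215 of them called, 3407 were the same, 1305 weaker and 17 stronger. All 32 list calls were lost with an estimated correlation, 14 with quantile normalization and 7 with the block, while fry added 23 and lost 2.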

Other observations

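Families in this part were chosen after the data were seen. Most metallothioneins, small proteins that bind zinc and copper, rose with NaB and with the combination: of 9 measured, 6 and 7 were called higher and none lower, with medians of 1.04 and 1.25. MT1B rose by 1.04 and 1.25, MT1X by 0.98 and 0.95 and MT1L by 1.1 and 1.16, while MT1F stood at 0.19 and -0.08. With VP-16 none was called and the median was 0.50. In the blocked fit of NaB the adjusted p of MT1G, MT2A and MT1E was 0.0516, 0.0549 and 0.0573. Their changes with NaB were 1.05, 1.14 and 0.75 with normexp, where MT1E did not pass, 1.25, 1.1 and 1.16 with quantile normalization, and 1.23, 1.26 and 1.15 with median scaling.

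Among immediate early genes, which cells switch on within minutes of a stimulus, many were called lower. Of 18 measured, 11 were called lower with VP-16, 11 with NaB and 12 with the combination, with medians of -2.43, -1.97 and -1.75, and the family was not tested as a set. NR4A1, a nuclear receptor, changed by -2.59, -2.12 and -1.54 and DUSP1, a phosphatase of MAP kinases, by -1.63, -1.39 and -2.00, whereas JUNB stood at -0.30, -0.21 and -0.39, BTG2 at -0.11, 0.66 and 0.25, IER3 at 0.16, -0.21 and 1.73 and ZFP36 at -0.69, 0.30 and 0.09 without a call. The 3 values share the untreated arrays. JUN fell with NaB by 1.95 with normexp, by 2.57 with quantile normalization and by 2.56 with median scaling.

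The arrays of the second slide had fewer spots well above background, 57.1% to 60.6% beside 63.1% to 64.5%, and 13 to 124 saturated spots beside 6 to 14.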
